A study of Mus musculus with 13 samples.

How the data were processed

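RNA was measured by bulk sequencing in 13 mouse libraries that the labels place in 6 groups. Female extraembryonic endoderm (XEN) lines, grown in DMEM with serum per the labels, were wild type (2 libraries), wild type with 20 uM 5-aza-2'-deoxycytidine (2), deleted for the paternal Xist allele (3), or deleted and treated (2). Female epiblast stem cells (EpiSC), grown on matrigel with FGF2 and Activin, were wild type (2) or heterozygous for an Xist deletion (2). Total RNA was taken with Trizol. The labels name NEBNext Ultra and TruSeq stranded kits without saying which library had which. Whether replicates were separate clones, cultures or preparations is not given in the sources used here, so the p-values measure only the spread between these libraries.

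The deposited table holds the count of reads per gene, with no normalisation, for 38377 gene identifiers. The submitters' notes name FastQC, STAR 2.7.9a and featureCounts 2.0.1 on GRCm38 (mm10). The counting strand, the handling of multi-mapped reads and the annotation release are not given in the sources used here. Raw reads and allele-resolved counts were not analysed here, so no value separates the parental X chromosomes, and reads of Xist and of the antisense gene Tsix cannot be assigned where these genes overlap. Symbols, positions and gene classes came from GENCODE vM21 on GRCm38, which matched 38240 identifiers (99.64%). The other 137 kept their identifiers alone.

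Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr on the groups in the fit, and the quasi-likelihood F test with robust dispersion. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 9 XEN libraries shared 1 fit (5 residual degrees of freedom), the 4 EpiSC libraries another (2), and the 9 untreated libraries of both cell types the last (5). Standard errors are the absolute log2 fold change over the square root of F. Levels are in CPM, counts scaled by TMM to library size, given as mean ± SD over the n libraries of a group. Where a group held 0 counts of a gene, a fold is a lower bound from a floor of 3 counts over the group. With 1 to 3 counts the ratio is given with its exact 95% counting interval. Intervals and floors cover counting error only. Totals ran from 5848454 to 35247432 counts per library, and 3 counts in 1 library were 0.498 CPM in the shallowest and 0.0815 CPM in the library with the lowest floor.

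The X-linked shift is the median log2 fold change of X-linked genes (Xist and Tsix left out) minus that of autosomal genes. X-linked genes were compared with all others by camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, and called genes by Fisher's exact test (two-sided). With an estimated correlation camera also takes its p-value on the residual degrees of freedom of the fit. These are few here, so a call can be lost whatever the correlation. Camera p-values of the X-linked class were adjusted over the 8 comparisons, and those under an alternative are unadjusted. Shifts of single libraries were taken against the wild-type mean of the cell type, on genes of at least 10 CPM with 0.2 CPM added, with 95% intervals from 2000 bootstrap draws of genes. These intervals do not cover the spread between libraries. The same procedure gave a profile of each chromosome, and windows of 10 Mb described the X.

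There were 22 gene lists: X-inactivation centre, XCI escape genes, X-linked housekeeping genes, X-linked germline and placental clusters, Polycomb complexes, DNA methylation machinery, Methylation-silenced germline genes, Imprinted genes, Interferon response genes, p53 target genes, Cell cycle genes, Integrated stress response genes, markers of extraembryonic, visceral and parietal endoderm, epiblast, naive pluripotency, germ layers, trophoblast and fibroblasts, Endogenous retrovirus-linked 2-cell genes, and Y-linked genes. Lists with at least 5 tested members were tested by camera and by fry, adjusted over the lists of a comparison. Fry asks whether a list's genes move one way on balance, and its mixed test whether they change either way, without reference to other genes. List members were counted over all genes and adjusted over the list alone. Xist and Tsix could be members of the X-inactivation centre list alone, so tests of that list include the deleted gene.

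The groups, 8 comparisons, tests, lists and most alternatives were fixed before the data were examined. Named genes followed a rule fixed then too: Xist and Tsix, the called genes with the largest folds (up to 8 X-linked higher, 4 X-linked lower and 6 autosomal each way, or 4 each way in interactions) with a mean of at least 1 CPM, no overlap between the compared libraries and a gene symbol, and up to 4 members of each list with the smallest adjusted p. In EpiSC against XEN only marker-list members were named. Results for 2 genes that met the rule are not reported here and do not enter the tallies of named genes. Chosen after the data were seen were the library-type term, the correction for GC content (a loess trend on autosomal genes per library), and the fits without histone and small RNA genes.

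Alternatives were size factors by the RLE method, TMM on autosomal genes, no filter, a mean of at least 5 CPM, a block on replicate number, the contrast's own groups alone, all 13 libraries in 1 fit, DESeq2 1.42.0, an X-linked floor of 10 CPM, and leaving out each library in turn. Residuals of libraries with the same replicate number correlated at 0.798 in EpiSC, where number follows library type, and between -0.158 and 0.163 in XEN. Treated dXist XEN libraries carry the titles of dXist libraries 1 and 2 with AZA added, which pairs them by name. Beyond these titles, whether they are the same lines is not given in the sources used here. The main fit did not pair them, and dXist library 3 has no treated partner. Differences between libraries 1 and 2 of these groups correlated at 0.0454 (Pearson). Treated library 1 stood apart from the other libraries, so this correlation cannot tell whether the lines are the same.

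The procedure was tested on simulated data in 5 of the comparisons, with 200 changed genes each, in fits by group alone. Fits with a block on replicate number were not simulated. At the measured spread (biological coefficient of variation 0.474 to 0.524) none of the 2-fold genes was recovered by edgeR, and 4-fold genes only in EpiSC, 11 of 95, where 7 of 18 calls were false. The single call in deleted treated against deleted XEN was false. At a coefficient of 0.1 the recovery was 65.3% to 85.7% of 2-fold genes and 84.2% to 97.9% of 4-fold genes, with 6 to 10 false calls. A simulated X-linked shift of 0.5 came out at 0.447 to 0.513, and no shift at -0.08 to 0.03, with an estimated-correlation p of 0.0438 in XEN in the latter case.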

Results

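The series asks how loss of Xist, the RNA that silences 1 X chromosome in female cells, affects X-linked genes in extraembryonic endoderm (XEN) cells and in epiblast stem cells (EpiSC), and what the DNA methylation inhibitor 5-aza-2'-deoxycytidine (Aza) adds in XEN cells. The groups held 2 wild-type, 3 Xist-deleted (dXist), 2 treated wild-type and 2 treated dXist XEN libraries, and 2 wild-type and 2 dXist EpiSC libraries. Total counts were 30841285 and 35247432 in wild-type XEN, 34499305, 27917680 and 30972708 in dXist XEN, 5848454 and 9181835 in treated wild-type XEN, and 19349948 and 29533263 in treated dXist XEN. They were 35026481 and 18053287 in wild-type EpiSC and 29624511 and 19055996 in dXist EpiSC. Levels are in CPM, counts scaled to library size.

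Xist (X, 103460366 to 103483254 on GRCm38) was counted at 1550 and 1586 CPM in wild-type XEN libraries 1 and 2, and at 2.28, 1.16 and 4.78 CPM in dXist XEN libraries 1 to 3. Treated wild-type XEN libraries held 1626 and 1214 CPM, and treated dXist XEN libraries 14.6 and 242 CPM. EpiSC libraries held 815 and 206 CPM in the wild type and 0.435 and 0.276 CPM in dXist. The dXist mean was 572-fold lower in XEN (2.74 ± 1.86 CPM, n = 3, against 1568 ± 25.6, n = 2, log2 change -9.15, SE 1.18) and 1437-fold lower in EpiSC (0.355 ± 0.112, n = 2, against 511 ± 431, n = 2). In XEN the adjusted p of Xist was 0.0602, with a range of 1.4e-58 to 0.304 over the alternatives, and 0.0195 without dXist library 3. Tsix (X, 103431517 to 103484957), the antisense gene that overlaps Xist, stood at 0.403 ± 0.286 CPM in wild-type and 4.82 ± 5.37 CPM in dXist XEN cells.

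**Figure D1:**
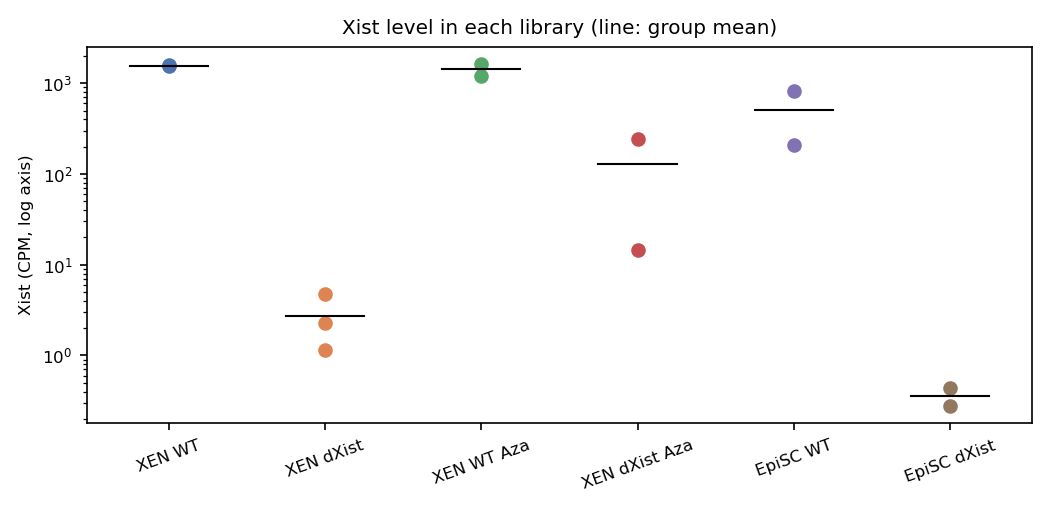
Xist level of each library in CPM on a log axis, by group, with the group mean. Wild-type libraries lie between 206 and 1626 CPM, untreated dXist libraries between 0.276 and 4.78 CPM, and the treated dXist XEN libraries at 14.6 and 242 CPM.

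Transcripts without poly(A) tails divided the libraries. Mitochondrial rRNA and the small nuclear RNA Rn7sk, both without the long tails that poly(A) selection needs, took 10.4% to 13.5% of counts in both treated wild-type XEN libraries and in EpiSC wild-type library 2 and dXist library 2. In the other 9 libraries they took 0.0152% to 0.279%. Histone genes, whose replication-dependent messages also lack the tail, took 0.706% to 1.18% in the first 4 and 0.0017% to 0.0143% in the 9. These 4 are called total-like and the 9 polyA-like. In EpiSC each genotype had 1 of each type. In XEN only the treated wild type was total-like, so its treatment and library type cannot be told apart inside XEN.

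**Figure D2:**
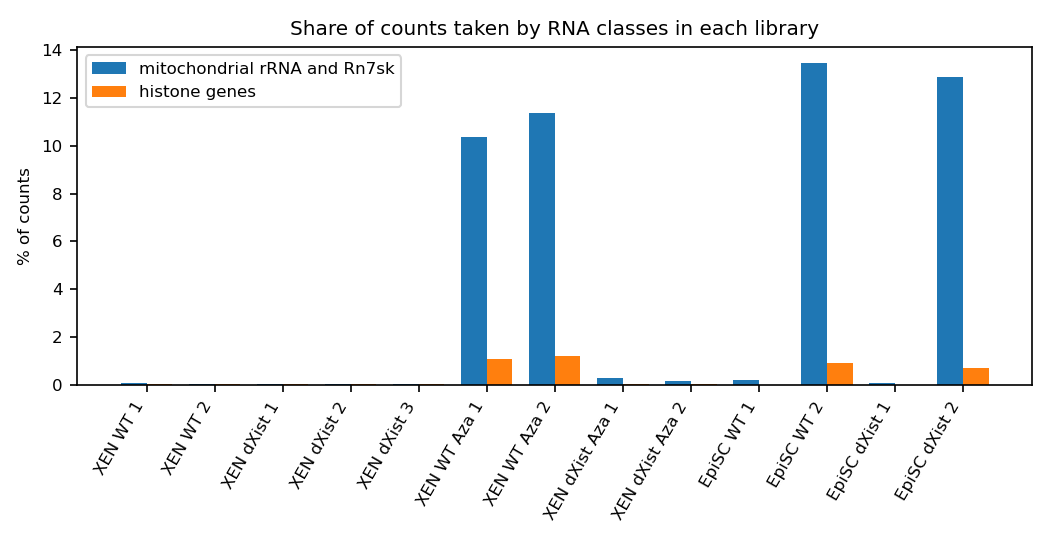
Bars of the share of counts in mitochondrial rRNA and Rn7sk and in histone genes for each library, in percent. By the former the 4 total-like libraries lie at 10.4% to 13.5%, apart from the 9 at or below 0.279%.

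Wild-type EpiSC and XEN libraries were compared to describe the cell types. The endoderm regulators Gata4 and Sox17 were at 1262 ± 98.9 and 628 ± 75.5 CPM in XEN (n = 2) and at 0.192 and 0.0867 CPM in EpiSC (n = 2, log2 change -12.72 and -12.97, both adjusted p = 3.2e-05). The basement-membrane gene Lama1 fell from 22194 ± 10478 to 8.66 ± 1.99 CPM. The epiblast gene Pou3f1 rose from 0.0829 to 108 ± 4.52 CPM (log2 change 10.29, SE 0.68). The imprinted gene Grb10, a signalling adaptor, was 16.6-fold higher in EpiSC (1228 ± 174 against 74.2 ± 13.4 CPM), and the maternally expressed noncoding RNA Meg3 stood at 829 ± 341 against 0.067 CPM. In all 3308 genes rose and 2777 fell among 19733. All 24 extraembryonic endoderm markers fell (24 also adjusted over the list alone, median -6.22, camera adjusted p = 1e-20, adjusted p = 0.00559 with an estimated correlation). Of 26 epiblast markers 21 rose and 1 fell (median 7.32, or 6.57 with genes at their bound), and of 18 fibroblast markers, which include collagens, 15 rose (median 7.47, or 6.63). X-linked germline and placental clusters had 12 of 22 members lower (median -6.87, or -4.69 with genes at their bound). These last 3 lists had adjusted p = 0.0302, 0.0367 and 0.0367 with an estimated correlation. X-linked genes rose more often than autosomal genes (27.9% against 16.4%, Fisher's exact p = 5.1e-13). The X-linked shift was 0.49 (camera adjusted p = 0.0279 over the 8 comparisons, adjusted p = 0.502 with an estimated correlation), while the median of all genes stood at 0.13. The shift was 0.37 (unadjusted p of 0.0705) without wild-type XEN library 2, 0.28 (0.184) without wild-type EpiSC library 1 and 0.25 (0.179) after GC correction. The count was 3811 without wild-type XEN library 1 and 3045 without wild-type EpiSC library 1.

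In dXist XEN cells 4 autosomal genes were lower than in the wild type. Grb10 (11, 11930508 to 12038683) fell 543-fold, from 74.2 ± 13.4 CPM (n = 2) to 0.137 ± 0.0297 CPM (n = 3), with a log2 change of -9.03 (SE 0.44, adjusted p = 4.6e-05), and it was called in 14 of 14 settings. Slc6a2 (8, 92960079 to 93001667), the noradrenaline transporter, fell 374-fold from 34.6 ± 16.8 to 0.0926 ± 0.0809 CPM. Emilin3 (2, 160906437 to 160912328), an extracellular matrix gene, fell 545-fold from 24.6 ± 25.7 to 0.0451 ± 0.0165 CPM. Rassf10 (7, 112953962 to 112957457), a Ras-association gene, was at 10.1 ± 0.376 CPM in the wild type and had 0 counts in dXist, at least 294-fold lower. The last 3 genes had adjusted p = 0.0148, up to 0.266 for Slc6a2 and Emilin3 and 0.290 for Rassf10 over the alternatives. No gene rose by edgeR among 18393, with 1973 genes at an unadjusted p under 0.05 and 506 called by DESeq2 (197 higher). The count of 4 became 25 without wild-type library 1, 2 without wild-type library 2, 1 without dXist library 1 or 2, and 510 without dXist library 3. Slc6a2 lost its call without wild-type library 2 (adjusted p = 0.0649), dXist library 1 (0.129) or dXist library 2 (0.10), Rassf10 without the same libraries (0.102, 0.0771 and 0.0800), and Emilin3 without dXist library 1 (0.140) or 2 (0.139).

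X-linked genes as a class stood higher in dXist XEN cells. Their median exceeded the autosomal median by 0.36 (629 genes, camera adjusted p = 0.000467 over the 8 comparisons, adjusted p = 0.153 with an estimated correlation), and 66.9% of them had a positive change against 49.5% of autosomal genes. By library the shift was 0.15 (95% interval 0.03 to 0.23), 0.10 (-0.05 to 0.22) and 0.37 (0.28 to 0.42). By the same measure wild-type libraries 1 and 2 lay at 0.099 and -0.099 around their own mean. Wild-type library 1 was thus as high as dXist library 2 and near dXist library 1. With libraries left out it lay between 0.21 and 0.46, and it was 0.31 after GC correction, 0.19 (unadjusted p of 0.0224) with a block on replicate number and 0.095 (0.00989) with no filter. Some autosomes stood as high as the X in dXist library 1 (chromosome 16 at 0.15, the X at 0.15) and library 2 (chromosomes 13, 2, 6, 4 and 12 at 0.55, 0.13, 0.12, 0.10 and 0.096, the X at 0.095). Positive medians were found in 17 of 18 windows along the X, and the change did not follow the distance to Xist (Spearman 0.01 across genes, which are not independent replicates). No X-linked gene was called by edgeR, and 85 were higher and 14 lower at an unadjusted p under 0.05. Called were 12 higher and 4 lower with the block, 16 and 8 without dXist library 3, 45 and 6 with no filter, and 35 and 5 by DESeq2. The smallest p-values among them, chosen after their values were seen, belonged to Armcx3, a mitochondrial protein gene, and Hs6st2, a heparan sulphate sulphotransferase. Armcx3 was at 3.79 and 1.24 CPM in the wild type and at 85.6, 31.3 and 46.4 CPM in dXist (adjusted p = 0.0990). Hs6st2 was at 8.34 and 14.7 CPM and at 64.3, 49.1 and 81.9 CPM (adjusted p = 0.115). None of the 40 X-linked housekeeping genes, 15 XCI escape genes or 28 X-linked germline and placental genes was called, and their medians were 0.31, 0.29 and 0.68 (camera adjusted p = 0.254, 0.709 and 0.212). In the X-inactivation centre list (8 tested, 0 called over all genes, 2 higher and 1 lower adjusted over the list alone, median 0.87, camera adjusted p = 0.445) Chic1 changed by 1.71 (SE 0.39, adjusted p = 0.248).

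**Figure D3:**
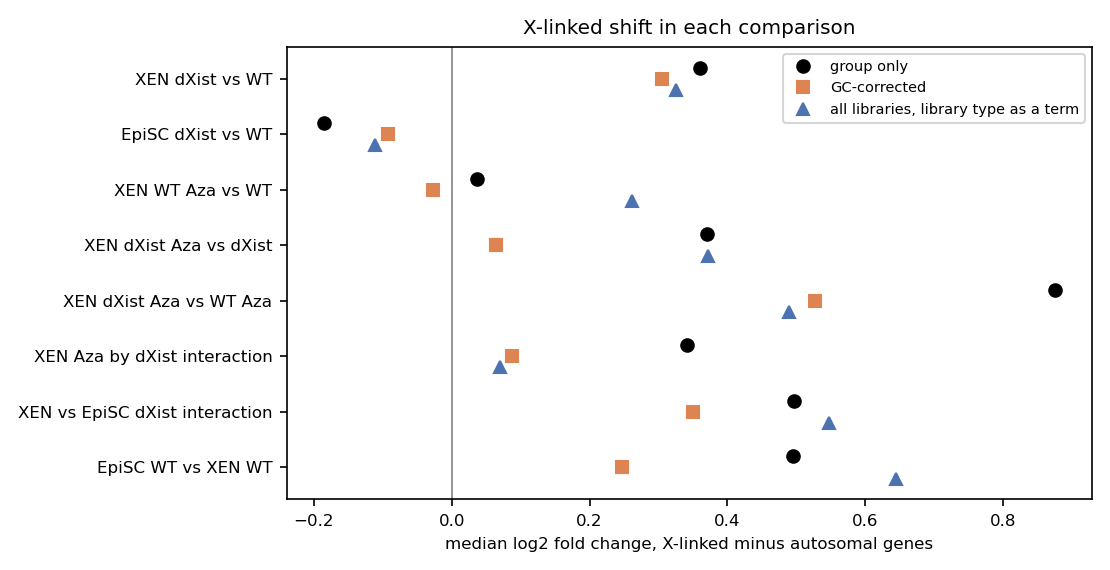
X-linked minus autosomal median log2 change of each comparison, with the values after GC correction and with library type as a term in a fit of all libraries. Without these the shift is 0.36 in dXist XEN cells, -0.19 in dXist EpiSC, and 0.88 in treated dXist against treated wild-type XEN cells.

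Gene lists in dXist XEN cells differed between classes. Cell cycle genes were lower as a list (35 tested, 29 negative, median -0.63, camera adjusted p = 2.0e-06, adjusted p = 0.564 with an estimated correlation), with 0 called over all genes and 15 lower adjusted over the list alone. The mitotic kinase gene Aurkb stood at 39.6 ± 10.8 CPM against 118 ± 46.4 in the wild type, and the cyclin gene Ccnb2 at 28.8 ± 7.52 against 77.8 ± 3.23. Integrated stress response genes, which ATF4 drives under amino acid or protein-folding stress, had 21 of 22 members positive (median 1.42, camera adjusted p = 0.000189, 0 higher adjusted over the list alone, adjusted p = 0.628 with an estimated correlation). Their median was 0.88 (adjusted p = 0.332) without wild-type library 1. The stress factor gene Atf3 stood at 466 ± 363 against 59.2 ± 22.0 CPM. Of 9 fibroblast markers 4 were lower adjusted over the list alone (median -2.01, or -0.96 with genes at their bound, adjusted p = 0.00188, adjusted p = 0.386 with an estimated correlation), among them the receptor gene Pdgfrb (1.52 ± 0.715 against 16.4 ± 0.552 CPM). The fibroblast list was at adjusted p = 0.104 without wild-type library 1 and 0.206 without wild-type library 2. Epiblast markers (18, median -0.75, adjusted p = 0.00594, 0.386 with an estimated correlation, 1 lower adjusted over the list alone) were at adjusted p = 0.272 without wild-type library 2 and 0.0752 without dXist library 3. For p53 target genes (30, median 0.92, adjusted p = 0.0190, 0.628 with an estimated correlation) the adjusted p was 0.0529, 0.206, 0.141 and 0.123 without wild-type library 1, wild-type library 2, dXist library 1 and dXist library 2. Interferon response genes (40, median 0.94, adjusted p = 0.0499, 0.716 with an estimated correlation) had a median of 1.06 (adjusted p = 0.348) without wild-type library 1 and -0.06 without dXist library 3. Imprinted genes (35, 1 lower over all genes, 1 higher and 3 lower adjusted over the list alone, median -0.02) included the placental growth gene Phlda2 at 1.96 ± 0.908 against 25.9 ± 5.72 CPM (adjusted p = 0.180). Medians of lists that camera did not call were 1.498 for Methylation-silenced germline genes (30 tested, 18 positive, 0.043 with genes at their bound, adjusted p = 0.384), -0.04 for Polycomb complexes, -0.15 for DNA methylation machinery, -0.16 for extraembryonic endoderm markers (2 lower adjusted over the list alone), 0.11 for visceral endoderm markers (where camera's direction was down), -0.44 for parietal endoderm and for naive pluripotency markers, -0.39 for germ layer markers and -0.50 for trophoblast markers.

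In dXist EpiSC genes were called by edgeR once library type entered the model as the replicate number. That number follows type in these 4 libraries, and the term leaves 1 residual degree of freedom. The fit was an alternative to the one fixed beforehand, which had no such term, and its false calls were not simulated. With that term the imprinted growth RNA H19 (7, 142575529 to 142578143) fell from 383 ± 67.5 to 34.7 ± 2.91 CPM (n = 2 each), by -3.71 and -3.18 in the polyA-like and total-like pairs (adjusted p = 3.1e-18). The collagen gene Col3a1 fell 27.2-fold from 142 ± 9.07 to 5.20 ± 0.591 CPM (-4.54 and -4.90). Hapln1 (13, 89539796 to 89611652), a matrix link protein, rose 157-fold from 0.445 ± 0.288 to 70.2 ± 16.7 CPM (6.60 and 7.05). On the X the phosphatase gene Dusp9 rose from 59.4 ± 34.6 to 192 ± 40.4 CPM (2.22 and 1.39), and Pir, a nuclear protein gene, from 5.38 ± 0.215 to 18.5 ± 0.104 CPM (1.71 and 1.78). Jpx, a noncoding neighbour of Xist, rose from 3.77 ± 0.421 to 10.4 ± 0.458 CPM (adjusted p = 0.00133). The pluripotency factor Pou5f1 rose from 232 ± 37.1 to 509 ± 131 CPM. The Nodal antagonist Lefty2 fell from 207 ± 73.8 to 17.3 ± 0.733 CPM. With the term 841 genes rose and 1119 fell (over all 17132 genes the changes in the 2 pairs correlated at 0.645 by Pearson and 0.525 by Spearman), while a fit of all 13 libraries with library type as a term called 2. Without any such term edgeR called 0 of 17132 genes (smallest adjusted p 0.102, for Xist), with 1741 at an unadjusted p under 0.05 and 492 called by DESeq2. The count without the term was 174 without wild-type library 2, 47 without dXist library 1 and 98 without dXist library 2, where Xist had adjusted p = 0.0219, 6.5e-05 and 1.7e-07.

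X-linked genes went both ways in EpiSC. With the type term 44 X-linked genes rose and 63 fell, which were 7.86% and 11.3% of those tested against 4.82% and 6.35% of autosomal genes (Fisher's exact p = 0.00198 and 2.4e-05). The class shift was -0.19 without the term (camera adjusted p = 0.122 over the 8 comparisons) and -0.18 with it (unadjusted camera p of 0.0911). It was -0.29 (95% interval -0.38 to -0.18) in the polyA-like pair and -0.07 (-0.13 to -0.02) in the total-like pair. Without wild-type library 1 the shift was 0.05, without wild-type library 2 it was -0.42 (unadjusted camera p of 0.00142), without dXist library 1 it was -0.29 (0.00211) and without dXist library 2 -0.076. It was -0.093 after GC correction, and -0.089 with the type term and GC correction. Positive medians were found in 5 of 18 windows. Lower X-linked genes included the receptor gene Gabra3 (1.95 ± 0.545 against 14.1 ± 8.36 CPM) and the proteoglycan gene Bgn (6.47 ± 1.87 against 34.0 ± 22.9 CPM).

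Several lists moved in EpiSC by camera in the fit without library type, with members counted in the fit with it. In the fit without it 0 members were called over all genes. Adjusted over the list alone, that fit had 9 fibroblast markers, 9 interferon response genes and 4 imprinted genes lower. It had 4 integrated stress response genes higher, and 1 parietal endoderm marker higher and 8 lower. Fibroblast markers fell (18 tested, median -1.10, camera adjusted p = 5.1e-07, 0.188 with an estimated correlation), with 10 lower over all genes and 11 adjusted over the list alone. Integrated stress response genes rose (22, median 0.78, adjusted p = 6.7e-07, 0.188 with an estimated correlation, 8 higher and 1 lower, 13 and 1 adjusted over the list alone), among them the kinase-like gene Trib3 (13.9 ± 1.26 against 2.08 ± 1.23 CPM). Interferon response genes fell (39, median -0.92, adjusted p = 4.6e-06, 0.188 with an estimated correlation, 1 higher and 15 lower, 3 and 18 adjusted over the list alone), among them Usp18 at 0.104 ± 0.0827 against 3.83 ± 1.98 CPM. Parietal endoderm markers (16, median -1.08, adjusted p = 3.8e-05, 0.204 with an estimated correlation) had 1 higher and 8 lower, 1 and 9 adjusted over the list alone. Imprinted genes (38, median -0.37, adjusted p = 0.0154, 0.492 with an estimated correlation) had 3 higher and 8 lower, 5 and 9 adjusted over the list alone. Germ layer markers (12, median -0.65, adjusted p = 0.0154, 0.321 with an estimated correlation) had adjusted p = 0.0741, 0.248 and 0.198 without wild-type library 1, wild-type library 2 and dXist library 2. Extraembryonic endoderm markers (19, median -0.39, adjusted p = 0.0168, 0.321 with an estimated correlation) had adjusted p = 0.0817, 0.0909, 0.0713 and 0.131 without wild-type library 1, wild-type library 2, dXist library 1 and dXist library 2. In the fit with library type camera called the same lists except Extraembryonic endoderm markers (adjusted p = 0.112). It also called the X-inactivation centre (9, median -0.06, adjusted p = 0.0110). That list holds the deleted gene Xist, with 1 member higher and 1 lower over all genes and a mean of -0.88. With an estimated correlation camera called no list in that fit (smallest adjusted p 0.737). A correlation cannot be estimated well from 1 residual degree of freedom, so this decides nothing about the lists. Epiblast markers were called in neither fit (26, 4 higher and 1 lower, median -0.11 with the term, adjusted p = 0.773). Imprinted genes had adjusted p = 0.118 without wild-type library 1 and 0.0545 without dXist library 2. Of 33 Polycomb genes 4 rose, over all genes and adjusted over the list alone, among them Ezh1 (56.9 ± 2.40 against 21.1 ± 0.117 CPM) and Cbx7. The list was not called (camera adjusted p = 0.965 with library type in the fit).

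Treated and untreated wild-type XEN libraries differed in library type as well as in Aza. Treated libraries 1 and 2 correlated at 0.993 (Spearman, across genes), against 0.944 for the untreated pair. Whether the treated pair came from separate cultures is not given in the sources used here. Its SDs may therefore understate the spread between cultures. Kcnq1ot1 (7, 143203458 to 143296549), an imprinted noncoding RNA expressed from the paternal allele, where it silences neighbouring genes in cis, rose 18.0-fold from 7.12 ± 3.59 to 128 ± 52.6 CPM (n = 2 each, log2 change 4.25, SE 0.77, adjusted p = 0.0488). Rian (12, 109603940 to 109661716), from the Dlk1-Meg3 domain, rose from 2 counts over the untreated group to 8.72 ± 1.06 CPM, a ratio of 272 with a counting interval of 73.8 to 2267 (log2 change 7.92, SE 1.29, adjusted p = 0.0253). Its neighbour Meg3 stood at 7.33 ± 0.736 against 0.067 ± 0.0947 CPM (adjusted p = 0.0558). The poly(A)-binding protein gene Pabpc4 (634 ± 22.7 to 150 ± 6.99 CPM), the histone chaperone gene Anp32b (413 ± 114 to 44.8 ± 8.95 CPM), the Wnt-pathway repressor gene Tcf7l1 (148 ± 47.2 to 32.8 ± 6.96 CPM) and Proser1 (44.6 ± 0.124 to 10.1 ± 0.641 CPM) fell. In all 101 genes rose and 6 fell, and 91 of the higher genes were histone or small RNA genes, such as Rn7sk at 28235 ± 1848 against 0.675 ± 0.278 CPM. With library type as a term Rian had a log2 change of 7.56 (SE 0.87, adjusted p = 0.0479) and was the 1 gene called, while Kcnq1ot1 changed by 2.25 (SE 0.90) and Pabpc4 by -1.42 (SE 0.45, both adjusted p = 1). Untreated EpiSC of the total-like type were lower than the polyA-like ones for Anp32b (-2.87), Tcf7l1 (-1.88) and Proser1 (-2.05), by -0.66 for Pabpc4, and higher for Kcnq1ot1 (1.91). Each of these 6 genes lost its call when any of the 4 libraries was left out, with Rian at adjusted p = 0.0894 and 0.147 without wild-type library 1 and 2 and 0.128 and 0.170 without treated library 1 and 2. Over the alternatives the adjusted p of Rian reached 0.170 and that of the other 5 reached 1. The count was 44 and 55 without wild-type libraries 1 and 2 and 61 and 55 without treated libraries 1 and 2. Without histone and small RNA genes edgeR called 0 genes, with 2086 at an unadjusted p under 0.05, and DESeq2 called 646 in the whole set.

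Methylation-silenced germline genes, whose promoters are methylated in somatic cells, stood higher in treated wild-type cells (30 tested, 27 positive, median 4.17, or 3.29 with genes at their bound, camera adjusted p = 1.9e-07, adjusted p = 0.351 with an estimated correlation), with 0 called over all genes or adjusted over the list alone. The list's median was 3.88 (adjusted p = 9.2e-11) with library type as a term. Inside XEN type and treatment coincide, so that term rests on the EpiSC libraries. There 10 of the 41 listed genes passed the filter, and for the others the term can hardly separate type from treatment. Dazl, a germ cell RNA-binding gene, was at 2.07 ± 0.112 against 0.067 ± 0.0947 CPM (adjusted p = 0.210). Interferon response genes were positive for 38 of 40 (median 1.96, adjusted p = 3.2e-06, 0.521 with an estimated correlation, 1.60 with library type), with 0 adjusted over the list alone. The guanylate-binding gene Gbp3 stood at 6.22 ± 0.335 against 0.852 ± 0.168 CPM. Imprinted genes (35, 2 higher over all genes, 6 higher adjusted over the list alone, median 0.38, adjusted p = 0.0150, 0.276 with an estimated correlation) had a median of 0.68 with library type. Polycomb complexes (median -0.45), p53 target genes (0.58) and Cell cycle genes (-0.39) each had adjusted p = 0.0248, and Extraembryonic endoderm markers (-0.49) and X-linked housekeeping genes (-0.22) adjusted p = 0.0285. With an estimated correlation these 5 lists had adjusted p = 0.276, 0.597, 0.597, 0.476 and 0.422. Without wild-type library 2 their camera p-values were 0.111, 0.246, 0.440, 0.440 and 0.352, and without treated library 2 they were 0.0836, 0.0684, 0.0684, 0.109 and 0.0836. The X-linked shift was 0.04 (camera adjusted p = 0.529 over the 8 comparisons), -0.04 without wild-type library 2, 0.26 (unadjusted p of 0.0253) with library type as a term, and -0.11 (0.0153) for X-linked genes of at least 10 CPM.

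Treated dXist XEN cells differed from untreated ones in 14 genes, each at adjusted p = 0.0498. Cubn (2, 13276338 to 13491813), the endocytic receptor of visceral endoderm, rose from 50.1 ± 16.9 CPM (n = 3) to 337 ± 3.02 CPM (n = 2, log2 change 2.59, SE 0.36). The receptor gene Notch1 rose from 2.83 ± 1.64 to 34.3 ± 3.64 CPM, the glucuronosyltransferase gene Ugt2b34 from 7.25 ± 1.498 to 102 ± 14.9 CPM, and the RNA-binding gene Celf5 from 2.24 ± 0.337 to 24.0 ± 0.667 CPM. Grb10 rose 12.1-fold from 0.137 ± 0.0297 to 1.66 ± 0.431 CPM (log2 change 3.38, SE 0.40), against 74.2 ± 13.4 CPM in the untreated wild type. The X-linked kinase gene Pak3 (X, 143518591 to 143797796) rose from 0.0790 ± 0.0473 to 8.80 ± 6.80 CPM. Dus3l, a tRNA-modifying enzyme gene, fell from 65.8 ± 11.8 to 11.9 ± 2.46 CPM. This fit did not pair the treated libraries with dXist libraries 1 and 2 by their titles, and dXist library 3 has no treated partner. In all 13 genes rose and 1 fell, and 4921 genes had an unadjusted p under 0.05. With RLE size factors the split was 24 higher and 5 lower, and with autosomal TMM 14 and 3. The count was 0 by edgeR without dXist library 1, dXist library 2 or treated library 1, 414 without dXist library 3, 4730 without treated library 2, 131 (90 higher and 41 lower) with a block on replicate number, 1393 with library type as a term and 2905 by DESeq2. Without dXist library 1 Cubn had adjusted p = 0.183 and Grb10, Notch1, Ugt2b34, Celf5, Pak3 and Dus3l 0.175. Without dXist library 2 all 7 had 0.179, and without treated library 1 they lay between 0.0868 and 0.120. In the fit of all 13 libraries with library type the adjusted p was 0.00479 for Grb10 and Pak3 and 0.00687 for Cubn. Both groups compared here are polyA-like, so the term cannot adjust this comparison, and that fit differs by its added libraries. Over the alternatives Grb10 ranged from 9.7e-07 to 0.179 and Cubn from 7.6e-09 to 0.183.

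The germline list stood higher here too (30 tested, 26 positive, median 2.29, camera adjusted p = 5.2e-07, 0.338 with an estimated correlation, and 0.79 with adjusted p = 0.0436 without treated library 2), with 0 over all genes and 12 higher adjusted over the list alone. Sycp3, a synaptonemal complex gene, was at 5.90 ± 1.23 CPM against 1 count in 3 untreated libraries, a ratio of 536 with a counting interval of 95.5 to 21266 (adjusted p = 0.0584). Imprinted genes (35, 1 higher over all genes, 15 higher and 2 lower adjusted over the list alone, median 1.62, adjusted p = 0.000151, 0.0891 with an estimated correlation) included Kcnq1ot1 at 137 ± 128 against 7.26 ± 1.95 CPM. Integrated stress response genes were lower (22, 21 negative, median -2.19, adjusted p = 5.5e-05, 0.673 with an estimated correlation, 4 lower adjusted over the list alone), and at -1.44 (adjusted p = 0.0104) without treated library 1. That library stood apart, with 4.08% of counts in pseudogenes and 5.75% in mitochondrial protein genes, against 1.05% and 0.941% in treated library 2. Interferon response genes (median 0.87, adjusted p = 0.000991, 0.673 with an estimated correlation, 2 higher adjusted over the list alone) had a median of 0.08 (adjusted p = 0.237) without treated library 2. Fibroblast markers (9, median 2.00, adjusted p = 0.00405, 0.338 with an estimated correlation, 3 higher adjusted over the list alone) had adjusted p = 0.175 and 0.116 without treated library 1 and 2. Epiblast markers (18, median 0.92, adjusted p = 0.0417, 0.338 with an estimated correlation, 6 higher adjusted over the list alone) had adjusted p = 0.101 without dXist library 3 and 0.0612 without treated library 2. X-inactivation centre genes (8, median 0.54, adjusted p = 0.0454, 0.585 with an estimated correlation, 1 higher adjusted over the list alone) had adjusted p = 0.105, 0.124, 0.122 and 0.0612 without dXist library 2, dXist library 3, treated library 1 and treated library 2. The X-linked shift was 0.37 (camera adjusted p = 0.00600 over the 8 comparisons, adjusted p = 0.224 with an estimated correlation), 0.17 without treated library 1 0.59 without treated library 2, 0.06 (unadjusted p of 0.301) after GC correction, and 0.51 with a block on replicate number (0.000889, or 0.0329 with an estimated correlation). By library it was 0.95 (95% interval 0.72 to 1.25) and 0.40 (0.30 to 0.50) against the wild-type mean.

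**Figure D4:**
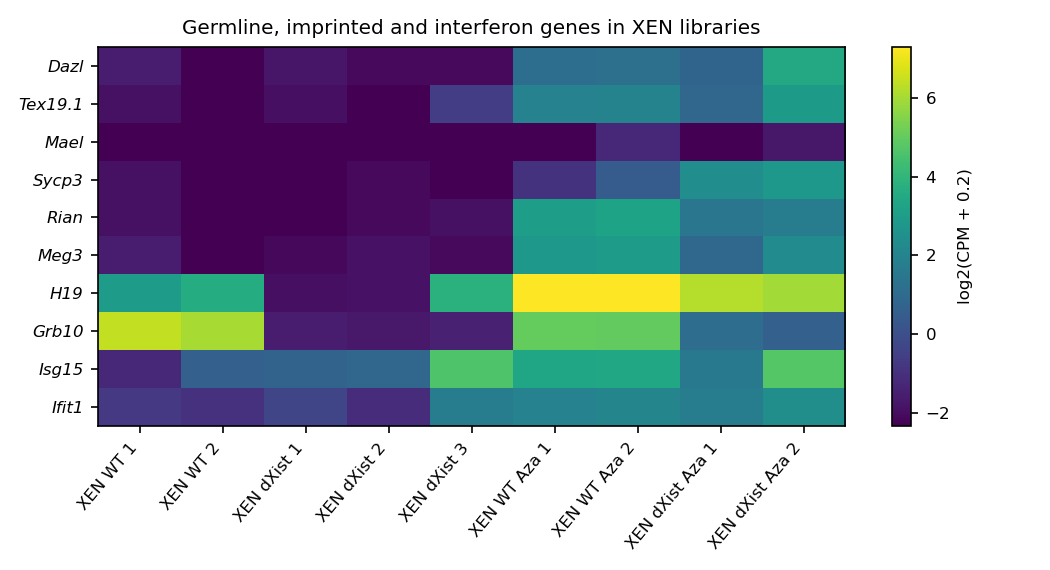
Heat map of selected germline, imprinted and interferon genes in each XEN library, coloured by the log2 of CPM with 0.2 added. Rian lies at 8.72 and 2.85 CPM on average in treated wild-type and treated dXist cells, and Grb10 at 74.2 and 0.137 CPM in untreated wild-type and dXist cells.

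Treated dXist cells were compared with treated wild-type cells, and the 2 genotypes' responses with each other. Grb10 was lower in treated dXist cells, at 1.66 ± 0.431 against 31.9 ± 0.889 CPM (n = 2 each, log2 change -4.52, SE 0.42, adjusted p = 0.000974), also with library type as a term (-4.44, adjusted p = 0.0246, and up to 0.0697 over the alternatives). On the X the Rab escort gene Chm rose from 18.2 ± 0.784 to 117 ± 56.6 CPM, the formin gene Diaph2 from 11.03 ± 3.43 to 68.4 ± 29.8 CPM and the noncoding gene Kantr from 3.89 ± 1.502 to 35.7 ± 9.13 CPM, and the Wnt acyltransferase gene Porcn fell from 57.7 ± 3.33 to 6.73 ± 1.97 CPM. In all 11 genes rose and 108 fell, 96 of the latter histone or small RNA genes, and 3 of the 11 were X-linked (Fisher's exact p = 0.00540). Chm, Diaph2, Kantr and Porcn had adjusted p = 1 with library type as a term, and Chm had 0.477, 0.497 and 0.0698 without treated wild-type library 1, treated wild-type library 2 and treated dXist library 1. The other 3 lost their calls without the same libraries, Diaph2 at 0.286, 0.795 and 0.104, Kantr at 0.552, 0.273 and 0.108, and Porcn at 0.191, 0.244 and 0.195. The X-linked shift was 0.88 (camera adjusted p = 3.0e-10 over the 8 comparisons, adjusted p = 0.0563 with an estimated correlation), beside a median of all genes of -0.10. It was 0.49 with library type, 0.53 after GC correction and 0.62 to 1.0 when libraries were left out. The count of 119 became 67 and 53 without treated wild-type library 1 and 2, 65 without treated dXist library 1 and 3321 without treated dXist library 2. DESeq2 called 1128 genes. Camera called no list (smallest adjusted p 0.0610). Fry called 1 for a shift to one side, XCI escape genes (15, 13 positive, median 0.60, fry adjusted p = 0.0103), and 3 for change either way.

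The response to Aza differed between genotypes for 45 genes by the interaction, 43 of them histone or small RNA genes that were lower. The exceptions were Grb10, which was higher (log2 difference 4.51, SE 0.55, adjusted p = 0.00678), and the ribosomal pseudogene Rpl38-ps2 (-3.88, adjusted p = 0.0347), which is named here after its value was seen. Grb10 was at 74.2 ± 13.4 CPM untreated and 31.9 ± 0.889 CPM treated in the wild type, and rose in dXist. With library type as a term edgeR called 0 genes for this difference, and Grb10 had adjusted p = 0.156, the highest of a range from 8.4e-08. Grb10 had adjusted p = 0.0557, 0.115 and 0.137 without wild-type library 1, treated wild-type library 1 and treated wild-type library 2. The count was 28 without treated wild-type library 2 and 1605 without treated dXist library 2, 1472 genes had an unadjusted p under 0.05, and DESeq2 called 218. Across all 18393 genes the changes with Aza in the 2 genotypes correlated at 0.519 (Pearson) and 0.478 (Spearman), with 2 shared higher genes against 0.0714 by chance (hypergeometric p = 0.00224). Without histone and small RNA genes 1 was shared, against 0.00666.

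XEN and EpiSC differed in the change between dXist and wild type for 2 of 19733 genes. Grb10 fell in XEN, and the change differed from that in EpiSC (log2 difference -8.68, SE 0.52, adjusted p = 0.000447). Aga (8, 53511727 to 53523421), a lysosomal amidase gene, was at 103 ± 10.1 against 85.4 ± 8.40 CPM in XEN and at 0.0596 ± 0.0459 against 4.02 ± 0.822 CPM in EpiSC (3 counts in dXist, a ratio of 81.4 with a counting interval of 27.5 to 397, difference 6.38, SE 0.57, adjusted p = 0.00906). Aga lost its call without wild-type XEN library 2, dXist XEN library 1 or dXist EpiSC library 1, with an adjusted p of up to 0.153. At an unadjusted p under 0.05 there were 2041 genes, DESeq2 called 447, and a block on replicate number, which follows library type in EpiSC, gave 743 (334 higher and 409 lower in XEN, 24 and 10 of them X-linked). The count was 11 without wild-type XEN library 1, 1 without dXist XEN library 1 or dXist EpiSC library 1, 5 without dXist XEN library 2 and 670 without dXist XEN library 3. The X-linked shift was 0.50 higher in XEN (camera adjusted p = 0.000715 over the 8 comparisons, adjusted p = 0.310 with an estimated correlation) and 0.26 (unadjusted p of 0.0552) without wild-type EpiSC library 1. Among 481 X-linked genes tested in both cell types the changes correlated at -0.08 (Spearman, across genes), with 5 shared higher genes at an unadjusted p under 0.05 against 4.74 by chance (hypergeometric p = 0.527).

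Changes with Xist loss and with Aza in wild-type XEN share the untreated wild-type libraries, which alone makes them correlate. Their covariance across genes was 0.323, below the 0.461 to 0.509 of 20 simulated sets without change. Among X-linked genes it was 1.41, above the simulated 0.415 to 0.638, while their Pearson correlation of 0.422 lay inside the simulated 0.385 to 0.528. Higher in both at an unadjusted p under 0.05 were 11 X-linked genes, against 5.40 on average in the simulated sets (2 to 9). The sets held no change in any group, whereas 85 and 41 X-linked genes were higher with Xist loss and with Aza at that threshold. Over all genes their covariance was also above the measured one. They therefore cannot decide whether X-linked genes overlap beyond what the shared libraries bring.

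Chromosomes other than the X also differed between libraries, in medians given here minus the autosomal median of the library. Chromosome 13 stood at 0.55 in dXist XEN library 2 and at 0.54 and 0.58 in treated dXist libraries 1 and 2, and chromosome 15 at -0.44 in dXist XEN library 3. Treated dXist library 1 differed on many chromosomes, among them 7 (-0.75), 19 (-0.74), 15 (-0.60), 11 (-0.57), 18 (0.58) and 3 (0.53). Chromosome 13 was thus not set apart in that library, whereas in treated library 2 the next highest autosome was 16 at 0.22. The medians were not corrected for GC content. They therefore cannot tell copy number changes from a GC trend between libraries. In both dXist EpiSC libraries chromosomes 15 (0.33 and 0.37), 10 (0.29 and 0.26), 19 (0.26 and 0.27) and 11 (0.18 and 0.21) stood higher and chromosomes 6 (-0.28 and -0.28) and 18 (-0.18 and -0.23) lower.

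**Figure D5:**
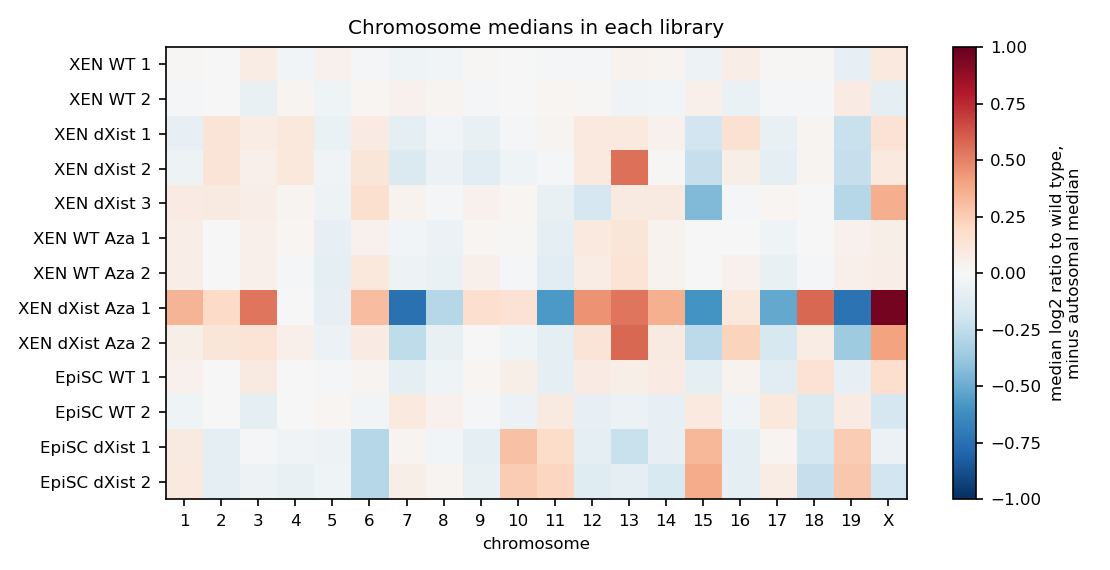
Median log2 ratio of each chromosome's genes to the wild-type mean of the cell type, minus the autosomal median of the library, without GC correction. Chromosome 13 reaches 0.58 in treated dXist XEN library 2, and the X reaches 0.95 over the autosomal median in treated dXist XEN library 1.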

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

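The tests for release of Xist from the intact allele, for gain of a whole X chromosome and for library type among histone and small RNA genes were chosen after the results were seen, as were the fits with library type and with a GC correction.

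The responses of wild-type and dXist XEN cells to Aza differed between these groups for 45 genes by edgeR's interaction term. Rn7sk (log2 difference -15.64), Hist1h3f (-17.08), Hist1h3h (-15.28) and Hist1h3i (-15.46) were lower in dXist. The 3 histone genes had 0 counts in treated dXist cells, so their fitted values are no bounds. Grb10 differed by 4.51 the other way. Only the treated wild type was total-like, and histone and small RNA genes mark that type. With library type as a term no gene was called by edgeR (Grb10 at adjusted p = 0.156), and without histone and small RNA genes the count was 0. The X-linked shift of the interaction was 0.34 (camera adjusted p = 0.000576 over the 8 comparisons, adjusted p = 0.153 with an estimated correlation), 0.070 (unadjusted p of 0.368) with library type as a term, 0.087 (0.0468) after GC correction and 0.16 (0.00190) without treated dXist library 1. Cell cycle genes had a median of 0.59 (camera adjusted p = 0.00741, 0.779 with an estimated correlation), with adjusted p = 0.338 without wild-type library 2 and 0.122 without treated dXist library 1.

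The difference between dXist and wild-type cells was not alike in XEN and EpiSC for 2 genes, Grb10 (-8.68) and Aga (6.38), and for 743 with a block on replicate number. The X-linked shift differed by 0.50. Interferon response genes differed by a median of 2.11 and Cell cycle genes by -0.76 (both camera adjusted p = 0.000306, 0.725 and 0.607 with an estimated correlation). Interferon response genes had a median of 0.74 (adjusted p = 0.0594) without dXist XEN library 3, and Cell cycle genes -0.50 (adjusted p = 0.0688) without wild-type XEN library 2. With groups of 2 and 3 libraries no library was tested for lying far from its group.

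Treated dXist XEN library 2 held Xist at 15.4% of the untreated wild-type level. Admixture of wild-type RNA would bring the abundant wild-type transcripts along, and 2 genes near absent from untreated dXist libraries 1 and 2 met the criteria for this, Grb10 at 1.82% and Myh7 at 2.27% of the wild-type level (median 2.05%). Myh7 was at 110 CPM in dXist library 3 and 60.02 CPM in treated library 1, so not all dXist lines lack it, but its 5.52 CPM in treated library 2 is the most that admixture could have brought there. Both genes lie below 0.5 of 15.4%, the bound set beforehand, which argues against admixture at the level that Xist would need. Release of Xist from the intact maternal allele by Aza may account for it, since treated library 1 also exceeded the highest untreated library (14.6 against 4.78 CPM). That library stood at 0.930% of the untreated wild-type level, far below library 2 under the same treatment, and the criterion was chosen after the values were seen. It therefore gives little support. No value here separates alleles.

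The X-linked shift of 0.36 in dXist XEN cells was set against technical causes. Against a GC trend between libraries as its whole cause stands the corrected shift of 0.31 (unadjusted camera p of 0.00155, or 0.0861 with an estimated correlation). Gain of a whole active X in all cells would put every library near 1, and the highest upper bound among the 3 was 0.42, under the 0.58 set for it. For treated dXist against dXist cells the shift of 0.37 became 0.065 (unadjusted camera p of 0.301) after GC correction, which is consistent with a GC trend. Derepression of part of the inactive X stays open as an untested candidate explanation for the first shift, beside gain of an X in part of the cells and differences between lines.

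Library type is a candidate explanation for most of the calls in treated wild-type XEN cells. Of 91 histone and small RNA genes called, 88 differed alike, in direction and by at least 0.5 of the size, between untreated EpiSC libraries 2 and 1. The types were set by mitochondrial rRNA and Rn7sk and described by histone genes. Genes of these classes are among the 91, so agreement for them was built in and is no independent evidence. Of the 16 other called genes 8 did, which is between the bounds set for either reading, so treatment and library type cannot be told apart for them as a group. Rian had 7.92 in XEN against 0.29 between those EpiSC libraries, and alone was still called with library type as a term (7.56). Prrg4 (3.31 against -0.023), Slc4a11 (3.33 against 0.32) and Igsf9b (2.65 against 0.30), named after their values were seen, also differed little between those libraries.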

How the results depend on the processing

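The library-type term, the GC correction and the sets without histone and small RNA genes were chosen after the data were seen. Among counts of called genes and X-linked shifts, 168 of the values under an alternative kept their direction and side of the threshold, 74 counts moved by over 1.5 times, 9 values were weaker, 3 stronger and 6 reversed. Of list medians 1539 were the same, 43 stronger, 95 weaker and 3 reversed in camera's direction (2 of them in the sign of the median), and of named genes 6326, 1034, 213 and 1. For lists and genes reversal was counted only where a value was called under a setting, and of the 6 reversed shifts 1 had an unadjusted p under 0.05. Among all 1680 list medians and 7574 gene values under an alternative, 177 and 11 changed sign without a call in either fit.

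Keeping every gene with a count raised the number called to 684 in dXist XEN, 676 in dXist EpiSC, 747 in treated wild-type XEN, 2750 in treated dXist against dXist, 885 in treated dXist against treated wild type, 337 for the Aza interaction and 616 for the cell-type interaction. DESeq2 gave 506, 492, 646, 2905, 1128, 218 and 447 in the same order. A mean of at least 5 CPM gave 28 in dXist EpiSC, 49 in treated dXist, 7 for the cell-type interaction and 3934 in EpiSC against XEN. The block on replicate number gave 368 in dXist XEN, 1960 in dXist EpiSC, 131 in treated dXist and 743 for the cell-type interaction.

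Fitting the compared groups alone gave 1 in dXist XEN, 927 in treated wild-type XEN, 0 by edgeR in treated dXist against dXist and 62 in treated dXist against treated wild type. With all XEN libraries in the fit, treated dXist against dXist had 4921 genes at an unadjusted p under 0.05 by edgeR and 2905 called by DESeq2. All 13 libraries in 1 fit gave 1 for the Aza interaction and 10 for the cell-type interaction. With library type as a term the counts were 31 in dXist XEN, 2 in dXist EpiSC (all 13 libraries), 1 in treated wild-type XEN, 1393 in treated dXist, 1 in treated dXist against treated wild type, 0 for the Aza interaction and 8 for the cell-type interaction. The libraries compared in dXist XEN and in treated dXist against dXist are all polyA-like, so there the term adjusts nothing. RLE size factors gave 29 in treated dXist and GC correction 150, and block with GC correction 2505 in dXist EpiSC. Without histone and small RNA genes the counts were 0 in treated wild-type XEN, 0 in treated dXist, 0 for the Aza interaction and 1 in treated dXist against treated wild type, where that set removes most of the called genes except in treated dXist. For the other alternatives the cause was not tested.

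The X-linked shift in treated wild-type XEN was 0 with no filter, -0.018 with its groups alone, 0.26 with library type, -0.027 after GC correction and -0.11 for X-linked genes of at least 10 CPM. In treated dXist it was 0.065 after GC correction and 0.18 for genes of at least 10 CPM, and for the Aza interaction 0.070 with library type. In EpiSC against XEN it was 0.22 with no filter, 0.25 after GC correction and 0.34 for genes of at least 10 CPM. The cause was not tested. At an unadjusted p under 0.05 the cell types shared 5 X-linked genes in place of 0, and Xist loss and Aza shared 210 genes in place of 0. Of the 210 genes 158 were higher and 52 lower. Simulated sets without change shared 137 higher (118 to 153) and 68 lower (57 to 86) on average. Interferon response genes in dXist XEN went to -0.030 with the block, and camera's direction for X-inactivation centre genes in dXist EpiSC turned down with it (median -0.058, against -0.081 without). The X-inactivation centre list holds the deleted gene Xist (log2 change -10.38 with the block). Of its 9 members 4 were positive and 5 negative with the block, with a mean of -0.88. With library type Hist1h2bn in treated wild-type XEN went to -0.75.

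Leaving out single libraries gave 1 to 510 genes in dXist XEN (shift 0.21 to 0.46), 0 to 174 in dXist EpiSC (-0.42 to 0.045), 44 to 61 in treated wild-type XEN (-0.042 to 0.081) and 0 to 4730 in treated dXist (0.17 to 0.59). It gave 53 to 3321 in treated dXist against treated wild type (0.62 to 1.0), 28 to 1605 for the Aza interaction (0.16 to 0.59), 1 to 670 for the cell-type interaction (0.26 to 0.85) and 3045 to 4864 in EpiSC against XEN (0.28 to 0.78). The lower ends of the counts were reached in dXist XEN without dXist library 1 or 2 and in treated dXist without dXist library 1, dXist library 2 or treated library 1, and the upper ends without dXist library 3 and treated library 2. Where a group was left with 1 library it was assumed to vary like the others. The median of interferon response genes in dXist XEN ran from -0.057, without dXist library 3, to 1.40. The shallowest library held 5848454 counts, where a floor of 3 counts is 0.498 CPM, so genes below it in treated wild-type XEN were not detectable at this depth in that library.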

Other observations

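Members of the integrated stress response list held values that did not pass over all genes. In treated dXist XEN cells the serine synthesis gene Phgdh was at 49.4 ± 36.8 CPM (n = 2) against 312 ± 167 CPM untreated (n = 3, log2 change -2.78, adjusted p = 0.0890). The mitochondrial folate genes Shmt2 and Mthfd2 had log2 changes of -2.73 and -2.35 (adjusted p = 0.0963 and 0.0915). In untreated dXist cells the stress gene Nupr1 stood at 125 ± 103 CPM (n = 3) against 6.84 ± 3.09 CPM (n = 2). The cystine transporter gene Slc7a11 had 2535 counts in the 3 dXist libraries and 2 in the 2 wild-type libraries, a ratio of 888 with a counting interval of 245 to 7334.

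Endoderm and germline genes held other values. Sox7, an endoderm factor, stood at 200 ± 8.77 CPM in dXist XEN against 587 ± 140 CPM in the wild type (adjusted p = 0.20). The X-linked germline gene Taf7l was at 6.20 ± 0.398 against 0.264 ± 0.148 CPM in treated wild-type XEN (adjusted p = 0.0911) and at 22.9 ± 18.4 against 0.611 ± 0.330 CPM in treated dXist XEN (adjusted p = 0.0584).

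Lists with under 5 tested members were not tested. Of 26 Endogenous retrovirus-linked 2-cell genes 22 were in the table and at most 3 were tested in a comparison, and the highest level was 2.66 CPM, of Duxbl1 in wild-type EpiSC library 2. Of 8 Y-linked genes 4 were in the table and 0 passed the filter, and the highest level was 0.307 CPM, of Uty in treated dXist XEN library 1.

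Replicate libraries differed in closeness. The chi-square per degree of freedom between replicates was 3.89 in treated wild-type XEN and 510 in treated dXist XEN. It was 75.5 between dXist XEN libraries 1 and 2, and 309 and 341 between each of these and library 3. Mitochondrial protein genes took 5.75% of counts in treated dXist XEN library 1 and 6.97% in wild-type EpiSC library 1. Jpx was at 26.9 and 5.98 CPM in dXist XEN libraries 1 and 2, and at 25.4 and 8.92 CPM in treated dXist libraries 1 and 2. Camera called 6 lists of 20 in dXist XEN, 7 in dXist EpiSC, 8 in treated wild-type XEN and 7 in treated dXist XEN, and 0 of these 28 with an estimated correlation. Fry called 0, 5, 1 and 6 lists for a shift to one side, and 7, 15, 5 and 16 for change either way. With the block on replicate number these were 0 and 4 in dXist EpiSC.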
